A study of Mus musculus with 96 samples.

How the data were processed

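Per the labels, macrophages were grown from bone marrow of male C57BL/6 mice 8 weeks old in conditioned medium with MCSF, given a small molecule 30 min before lipopolysaccharide (LPS) and lysed 4 h after LPS. Libraries of transcript 3′ ends were made with a modified SCRB-Seq and Nextera protocol, per the labels. The deposited table holds counts per gene symbol for 96 libraries, made by the authors from reads aligned with BWA to the mm10 build, per the submitters' processing notes. The BWA version, the gene annotation, any gene filter and whether PCR copies were collapsed by molecular identifier are not given in the sources used here. The values were checked to be whole numbers with another total in each library, so they were taken as unscaled counts. If copies were not collapsed, counts are not independent molecules.

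Groups were taken from the labels: NoStim (no LPS, wells A to D), DMSO with LPS, and 10 compounds with LPS (wells E to H), each with 8 libraries on 2 plates. Doses are not given in the sources used here, NoStim wells have no stated vehicle, and no compound was given without LPS. Compounds keep their label names, and the lists expected for each were set from the likely compound behind the label. The labels do not say whether a well name on both plates marks separate cultures or a shared lysate. Deviations of same-named wells correlated across plates in 12 of 12 groups (1561 genes, mean r 0.218, against 0.0578 for the same letter in another group). Results with those wells summed are therefore printed beside the counts.

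Tests used edgeR 4.0.16 in R 4.3.3: TMM scaling, genes kept by filterByExpr on the groups (4963 genes), 96 libraries in one model with group and plate, robust quasi-likelihood F tests, two-sided, and Benjamini-Hochberg adjustment over the genes of each comparison with a threshold of 0.05. Fold changes are log2 with the standard error of the fit, and CPM are counts scaled to a total of 1e+06. The 14 comparisons were LPS (DMSO against NoStim), each compound against DMSO, Tunicamycin against BrefA, ZVAD against Caspase-1 and Halofuginone against Tunicamycin. Depth and Rn45s share were compared by exact permutation of libraries. Gene lists were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, preset correlation 0.01), adjusted over 210 tests (lists with 5 or more tested members in 14 comparisons). Camera with an estimated correlation and fry were run beside it. The 23 lists were inflammatory, interferon, glucocorticoid-induced, NRF2, ATF4, tRNA synthetase, unfolded protein response, cyclic AMP, sterol synthesis, lysosome and autophagy, translation machinery, cell cycle, hypoxia and glycolysis, heat shock, p53 and macrophage identity genes, markers of 6 other cell types, and mitochondrially encoded genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

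Groups, comparisons, tests, lists, the naming rule and the first set of alternatives were fixed before the data were examined. The naming rule took, among genes past the threshold with 30 or more mean CPM in the higher group and the same sign on both plates, the 6 highest and 6 lowest fold changes (10 each for LPS, 4 each between compounds), skipping predicted genes. It added up to 4 passing members of each list with the largest changes and the 3 first-listed members of each expected list. The text names a subset of these genes, chosen after their values were seen. Gene coordinates are from GENCODE M21 (mm10), where 4743 of 4963 tested symbols were found.

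LPS-responsive genes (threshold and 2-fold) were called on one plate and compound effects measured on the other, because DMSO wells are shared. For the same reason fold changes were correlated across plates. As same-named wells may share a lysate, both were also computed with letters kept apart. Simulated with fitted spread and depth, the Baflo comparison recovered 17 of 67 genes changed 1.5-fold, 45 of 67 2-fold and 63 of 66 4-fold. It had 3 false calls among 128. With no change, 10 comparisons gave 1 call and 150 list tests 0, with no gene or well correlation simulated.

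Alternatives planned were RLE scaling, no plate term, no filter and a filter at 20 CPM, each plate alone, a replicate block, same-named wells summed, each well letter left out, fits of the compared groups alone, DESeq2 1.42.0, rules for failed libraries, and an estimated correlation for lists. Chosen after seeing the data were the Rn45s share as a covariate (with and without summed wells), Rn45s and Lars2 left out, DMSO wells split between contrasts, correlations between other letters on the other plate, the comparison of each library with group profiles, and the fits without Tunicamycin plate 2 F or without 3 wells (with Tunicamycin plate 1 H and BrefA plate 2 H). No library was left out of the results as reported, since 0 had a total under 10% of the median.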

Results

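Gene expression was measured in 96 libraries of mouse bone marrow-derived macrophages, in 12 groups of 8 (4 wells on each of 2 plates). Cells in 11 groups were given a compound or the vehicle DMSO for 30 min and then lipopolysaccharide (LPS), a bacterial cell wall component that macrophages sense, for 4 h. The remaining group, NoStim, got no LPS. Libraries were made from 3′ ends of transcripts, and the table holds counts of 23481 gene symbols, 7459 of them with no count in any library. The compounds are named as labelled: Dexa, Torin, tBHQ, pGE2, Baflo, ZVAD, Caspase-1, Halofuginone, BrefA and Tunicamycin.

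The total count per library ranged from 80196 to 379198 with a median of 257984.5, and 5939 to 10555 genes had a count. Rn45s, the ribosomal RNA precursor, took 19.2% of all counts and Lars2 2.91%. Halofuginone libraries held 0.377 times the DMSO total (exact permutation p = 0.000155, adjusted p = 0.00171, two-sided, over 11 groups) and 44.7% ± 3.20 Rn45s (SD, n = 8), against 19.4% ± 4.64 in DMSO libraries (exact permutation p = 0.000155, adjusted p = 0.00171). With same-named wells summed, n = 4 allows no exact p below 0.0286, the value found for both measures (adjusted p = 0.157 and 0.314). ZVAD libraries held 1.22 times the DMSO total (exact permutation p = 0.00109, adjusted p = 0.00598), which was also no longer past the threshold with wells summed (adjusted p = 0.157). Plate 2 libraries held more Rn45s than plate 1 libraries (22.8% ± 8.67 against 18.1% ± 8.59, SD), and the plate term was past the threshold for 317 genes higher and 401 lower on plate 2. Wells with the same treatment and letter deviated together across plates in all 12 groups (mean r across genes 0.218), so results with those wells summed to 4 per group stand beside the counts. The labels do not say that wells were separate cultures, and p-values measure the spread between wells.

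Library Tunicamycin plate 2 F stood apart. Its deviation from the mean of all groups on its plate had r = -0.0454 across 3045 genes with the profile of Tunicamycin wells on the other plate, where the median of the 96 libraries was 0.550 and the next lowest 0.186 (Tunicamycin plate 1 H). Its closest profile was NoStim (r = 0.340).

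**Figure D1:**
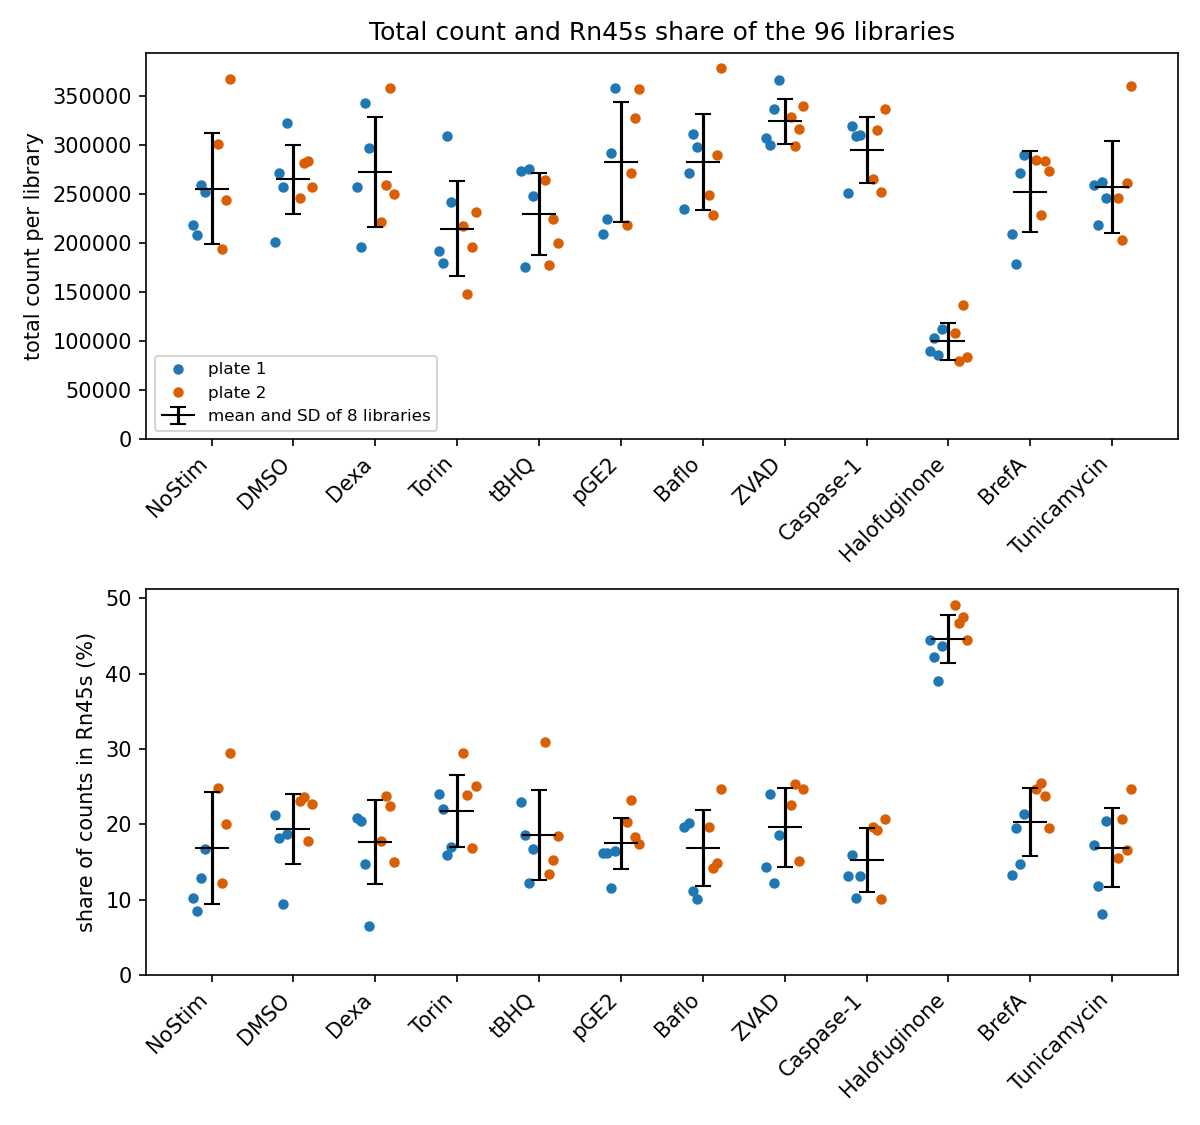
Total count (upper panel) and percentage of counts in Rn45s (lower panel) of each library by group, with points coloured by plate and bars for the mean and SD of 8 libraries. The 8 Halofuginone libraries have the lowest mean total and hold 39.0% to 49.1% Rn45s.

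DMSO wells with LPS were compared with NoStim wells for the response to LPS itself, and all fold changes are log2 ± SE from n = 8 wells per group. Highest and lowest refer to genes that meet the naming rule. Genes of the inflammatory response and of the interferon response rose together. The highest changes were in Ccl5 (a chemokine, ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518 of mm10; 4.86 ± 0.22), Fam26f (4.68 ± 0.24), Cish and Socs1, feedback inhibitors of cytokine signalling (4.61 ± 0.49 and 4.35 ± 0.30), Tnfaip2 (4.20 ± 0.16) and Rsad2, an antiviral enzyme (4.17 ± 0.20). Rhou (4.13 ± 0.42), Col27a1 (4.03 ± 0.52), the phosphatase gene Dusp2 (4.02 ± 0.19) and the chemokine gene Ccl2 (4.02 ± 0.22) followed. The lowest were in Vgll4 (-4.08 ± 0.37), the chemokine receptor gene Cxcr4 (-3.85 ± 0.22), Sesn1 (-3.77 ± 0.40), Susd3 (-3.62 ± 0.28), Lpar6 (-3.49 ± 0.47), and Zfp36l2, which promotes mRNA decay (-3.46 ± 0.28). Gpr65 (-3.10 ± 0.23), Fos (-3.06 ± 0.27) and Rab3il1 (-2.92 ± 0.44) were also among the lowest. Adjusted p was 1.17e-08 or less for each of these genes.

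Of 37 tested members of the inflammatory list, 36 rose and 0 fell (36 and 0 adjusted over the list alone). Their median was 2.63 (camera adjusted p = 1.27e-54, and 7.72e-08 with an estimated correlation). The cytokine genes Il1b (4.01 ± 0.15), Tnf (2.97 ± 0.14) and Il1a (1.32 ± 0.29) and the costimulatory receptor gene Cd40 (3.95 ± 0.19) were among them. In the interferon list 47 rose and 0 fell (47 and 0 over the list alone) of 47. Their median was 2.11 (adjusted p = 2.57e-46, and 0.000163 with an estimated correlation). Among these were Ifit1 (3.03 ± 0.16) and Ifit2 (1.61 ± 0.19). Lysosome and autophagy genes went the other way, as 1 rose and 16 fell (1 and 16 over the list alone) of 34 (adjusted p = 0.00248, but 0.162 with an estimated correlation). Among macrophage identity genes 1 rose and 7 fell (1 and 7 over the list alone) of 22 (adjusted p = 0.0339, but 0.214 with an estimated correlation). Cx3cr1, a chemokine receptor gene, was among those that fell (-2.86 ± 0.28), and Cd14, the LPS coreceptor, rose (1.19 ± 0.13). Translation machinery genes had 1 higher and 9 lower (1 and 7 over the list alone) of 47 (adjusted p = 0.0290, but 0.651 with an estimated correlation). LPS changed 1790 of 4963 genes, 968 higher and 822 lower. Of these, 1781 had one sign on both plates. Counts were 1520 on plate 1 alone, 882 on plate 2 alone and 1825 with same-named wells summed, 1550 of these shared. RLE scaling moved the median of all tested genes from -0.036 to -0.19 and gave 778 higher and 1248 lower, so that 38.4% in place of 54.1% were higher.

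**Figure D2:**
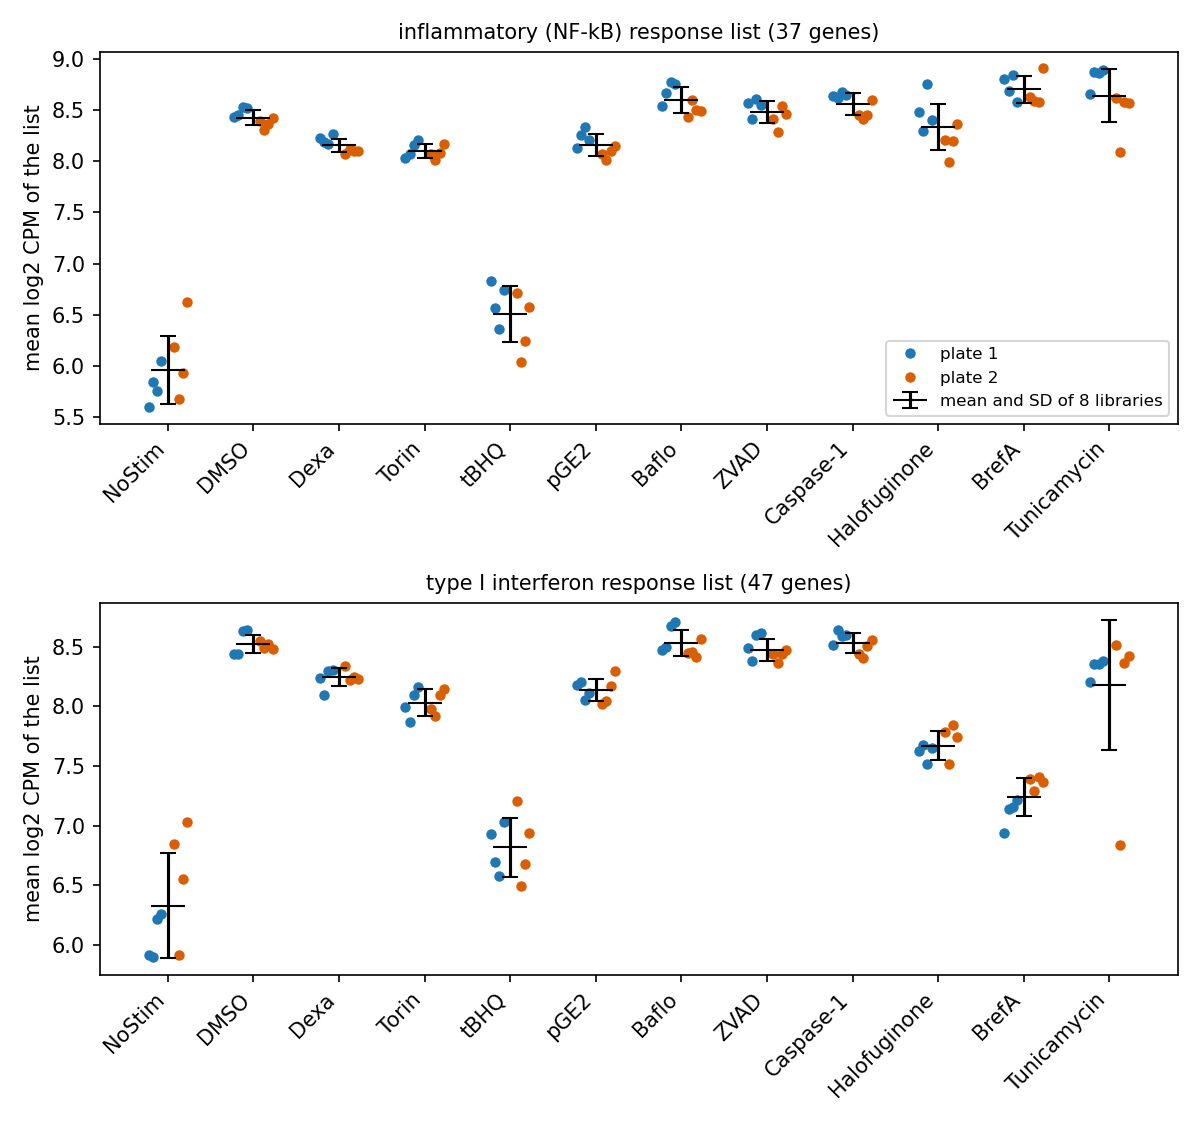
Mean log2 CPM of the inflammatory list (upper panel, 37 genes) and the interferon list (lower panel, 47 genes) in each library by group, with points coloured by plate and bars for the mean and SD of 8 libraries. NoStim and tBHQ wells lie lowest in both panels, BrefA wells are low in the lower panel, and Tunicamycin plate 2 F lies apart from its group.

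Each compound was compared with the DMSO wells that got the same LPS, which asks what it changed in stimulated cells. In Dexa wells the glucocorticoid-induced list rose and several cytokine genes fell. Tsc22d3, a glucocorticoid-induced anti-inflammatory regulator, had the highest fold change (ENSMUSG00000031431.13, chromosome X, 140539528 to 140600659; 3.90 ± 0.37, adjusted p = 1.80e-16). Klf9 (2.62 ± 0.36) and the metallothionein genes Mt1 (2.17 ± 0.17) and Mt2 (2.10 ± 0.17) were further members of that list. In it, 6 rose and 0 fell (6 and 2 over the list alone) of 13 (camera adjusted p = 6.68e-15, and 7.72e-08 with an estimated correlation). The cyclic AMP list had 4 higher and 1 lower of 13 (4 and 2 over the list alone; adjusted p = 0.000427, and 0.0186 with an estimated correlation). Klf4 (2.66 ± 0.23), the kinase gene Sik1 (2.69 ± 0.48), Fos (1.61 ± 0.30) and the phosphatase gene Dusp1 (1.22 ± 0.16) rose. Tns1, a cell adhesion gene (3.82 ± 0.28), and Saa3, an acute phase gene (2.36 ± 0.17), also rose. The transcription factor gene Irf8 (-2.56 ± 0.15) fell most, followed by Il1b (-2.16 ± 0.14), Cish (-2.00 ± 0.35), the adhesion molecule gene Vcam1 (-1.60 ± 0.40, adjusted p = 0.00435), Ier3 (-1.59 ± 0.23) and Mmp13 (-1.58 ± 0.25). In the inflammatory list 2 rose and 8 fell (2 and 13 over the list alone) of 37 (adjusted p = 8.76e-07, but 0.160 with an estimated correlation). Il12b (-1.46 ± 0.17) and Il1a (-1.08 ± 0.29, adjusted p = 0.0137, but 0.0554 with same-named wells summed) were among those that fell. Tnf did not pass (-0.20 ± 0.13, adjusted p = 0.571). For the interferon list 0 rose and 5 fell (0 and 7 over the list alone) of 47 (adjusted p = 2.41e-07, but 0.277 with an estimated correlation). Examples are Iigp1 (-0.82 ± 0.19, adjusted p = 0.00300) and Mx1 (-0.62 ± 0.17, adjusted p = 0.0218). Dexa changed 177 of 4963 genes, 97 higher and 80 lower. Of these, 177 had one sign on both plates. Counts were 101 on plate 1 alone, 48 on plate 2 alone and 151 with same-named wells summed, 138 of these shared.

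Torin wells had higher transcripts of the lysosome and autophagy list and lower transcripts of the interferon list, and neither call held with an estimated correlation. Gdf15, a stress-induced cytokine (ENSMUSG00000038508.7, chromosome 8, 70629393 to 70632456; 4.09 ± 0.32, adjusted p = 1.38e-22), Slc26a11, an anion transporter gene (3.83 ± 0.52), Hilpda, a lipid droplet gene (3.54 ± 0.34), Plau, the urokinase gene (3.54 ± 0.21), Bhlhe41 (3.40 ± 0.23) and Tnfrsf26 (3.39 ± 0.42) rose most. Of 34 lysosome and autophagy genes 12 rose and 1 fell (13 and 2 over the list alone) (camera adjusted p = 0.000669, but 0.105 with an estimated correlation). Those that rose included the folliculin complex genes Fnip1 (2.28 ± 0.21), Fnip2 (2.19 ± 0.15) and Flcn (1.80 ± 0.42) and the autophagy gene Gabarapl1 (1.41 ± 0.34). Lamp1 (0.049 ± 0.11), Lamp2 (0.12 ± 0.14) and Ctsa (0.055 ± 0.13) did not pass. Translation machinery transcripts had 8 higher and 0 lower (8 and 0 over the list alone) of 47 (adjusted p = 0.00313, but 0.554 with an estimated correlation). Rplp1 (0.51 ± 0.10) and Rps20 (0.50 ± 0.12) rose, and Rpl3 (-0.16 ± 0.15), Rpl4 (0.046 ± 0.11) and Rpl5 (0.10 ± 0.13) did not pass. The unfolded protein response list had 1 higher and 6 lower (1 and 10 over the list alone) of 28 and was lower as a list (adjusted p = 0.00896, and 0.0262 with an estimated correlation). Xbp1 fell (-1.10 ± 0.31) and Crebrf rose (1.88 ± 0.26). Interferon-response genes had 1 higher and 18 lower (1 and 21 over the list alone) of 47 (adjusted p = 1.26e-08, but 0.229 with an estimated correlation). Cxcl9 (-1.86 ± 0.23), Cmpk2 (-1.39 ± 0.19) and Cxcl10 (-1.35 ± 0.20) fell.

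Inflammatory genes in Torin wells had 3 higher and 12 lower (5 and 16 over the list alone) of 37 (adjusted p = 0.00248, but 0.389 with an estimated correlation). Ccl22 (-2.12 ± 0.43) and Il1b (-1.82 ± 0.14) were among the lowest, beside Vcam1 (-2.27 ± 0.47), the tubulin gene Tuba1c (-2.02 ± 0.23) and the lipase gene Lipg (-1.93 ± 0.23). Il10, an anti-inflammatory cytokine gene of the cyclic AMP list, rose (2.12 ± 0.24). That list had 4 higher and 1 lower (5 and 1 over the list alone) of 13 (adjusted p = 0.00970, but 0.104 with an estimated correlation). The NRF2 list had 0 higher and 4 lower (0 and 5 over the list alone) of 20 (adjusted p = 0.0146, but 0.285 with an estimated correlation). In the ATF4 list 4 rose and 2 fell (4 and 3 over the list alone) of 17, with no call for the list (adjusted p = 0.421). Atf3 rose (0.83 ± 0.15) and Atf4 did not pass (0.31 ± 0.17). Of the 4 tested sterol synthesis genes, too few for a list test, Insig1 rose (2.27 ± 0.17), while Hmgcs1 (0.35 ± 0.36) did not pass. Torin changed 830 of 4963 genes, 477 higher and 353 lower. Of these, 828 had one sign on both plates. Counts were 438 on plate 1 alone, 328 on plate 2 alone and 732 with same-named wells summed, 677 of these shared.

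In tBHQ wells the genes that LPS had raised were lower across nearly the whole of both response lists, and the heat shock list was higher. Of 37 inflammatory genes 0 rose and 36 fell (0 and 36 over the list alone). The median was -2.12 (camera adjusted p = 8.87e-43, and 2.39e-06 with an estimated correlation). Of 47 interferon-response genes 0 rose and 45 fell (0 and 45 over the list alone). Their median was -1.69 (adjusted p = 6.20e-36, and 0.000950 with an estimated correlation). The lowest fold changes were in Dusp2 (ENSMUSG00000027368.6, chromosome 2, 127336159 to 127338376; -4.00 ± 0.19, adjusted p = 8.33e-42), Fam26f (-3.82 ± 0.22), the matrix protease gene Mmp14 (-3.70 ± 0.30), the cytokine genes Il12b (-3.57 ± 0.22) and Il1b (-3.48 ± 0.15) and the feedback inhibitor gene Socs3 (-3.48 ± 0.18). Tnfaip2 (-3.39 ± 0.15), Ccl5 (-3.21 ± 0.19), Iigp1 (-3.07 ± 0.23) and Ifi205 (-3.02 ± 0.16) also fell. Among the highest were Slc26a11 (4.23 ± 0.48), Zfand2a, a proteotoxic stress gene (4.15 ± 0.36), Zfp36l2 (3.59 ± 0.28), Fos (3.41 ± 0.27) and Susd3 (3.32 ± 0.29). Heat shock genes had 6 higher and 2 lower (6 and 2 over the list alone) of 14 (adjusted p = 0.00566, and 0.0152 with an estimated correlation). Hspa1a (3.17 ± 0.24), Hspa1b (2.29 ± 0.21), Hsph1 (2.19 ± 0.36) and Hsp90aa1 (1.08 ± 0.12) rose. Lysosome and autophagy genes had 22 higher and 1 lower (24 and 1 over the list alone) of 34 (adjusted p = 1.84e-06, and 0.0168 with an estimated correlation). Among these were Flcn (2.71 ± 0.37), Fnip1 (1.76 ± 0.22), Gabarapl1 (1.56 ± 0.32) and the sialidase gene Neu1 (1.31 ± 0.24).

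The NRF2 list had 8 higher and 4 lower (8 and 5 over the list alone) of 20 and no call as a list (adjusted p = 0.0815). Hmox1, the heme oxygenase gene, rose (2.55 ± 0.17, adjusted p = 1.69e-28), as did the ferritin gene Ftl1 (0.90 ± 0.10) and the glutathione synthesis gene Gclm (0.55 ± 0.20, adjusted p = 0.0192), while Txnrd1 (-0.95 ± 0.13) and the cystine transporter gene Slc7a11 (-1.04 ± 0.38, adjusted p = 0.0229) fell. tBHQ changed 1807 of 4963 genes, 858 higher and 949 lower. Of these, 1805 had one sign on both plates. Counts were 1209 on plate 1 alone, 1114 on plate 2 alone and 1836 with same-named wells summed, 1529 of these shared. With RLE scaling the median of all tested genes was 0.19 in place of 0.044, and 1242 genes were higher and 766 lower (61.9% higher in place of 47.5%).

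In pGE2 wells the cyclic AMP list rose, and Tnf and several chemokine genes fell. Procr, the protein C receptor gene, had the highest fold change (ENSMUSG00000027611.12, chromosome 2, 155751117 to 155755471; 4.30 ± 0.23, adjusted p = 1.29e-36), followed by Dusp14 (4.11 ± 0.39), Flrt3 (3.90 ± 0.29), Hilpda (3.67 ± 0.33), the matrix glycoprotein gene Thbs1 (3.61 ± 0.21) and Ddit4 (3.60 ± 0.39). Of 13 cyclic AMP genes 10 rose and 1 fell (10 and 1 over the list alone). The median was 1.23 (camera adjusted p = 7.58e-20, and 3.53e-09 with an estimated correlation). The polyamine synthesis gene Odc1 (3.07 ± 0.16), Cd14 (2.22 ± 0.13) and Fos (2.19 ± 0.29) rose, and Nr4a1 did not pass (1.23 ± 0.73, adjusted p = 0.330). The hypoxia and glycolysis list had 7 higher and 0 lower (9 and 0 over the list alone) of 19 (adjusted p = 0.000228, and 0.0186 with an estimated correlation). Among these were the lactate exporter gene Slc16a3 (1.91 ± 0.27), Vegfa (1.17 ± 0.30) and Ndrg1 (1.05 ± 0.19). The glucocorticoid-induced list had 6 higher and 2 lower (7 and 2 over the list alone) of 13 (adjusted p = 0.00251, and 0.0395 with an estimated correlation). One example is Mt1 (1.47 ± 0.17). The lowest fold changes were in Edn1, an endothelin gene (-3.46 ± 0.33), Il12b (-3.17 ± 0.20), Ppargc1b (-2.63 ± 0.32), Irf8 (-2.54 ± 0.15), Ccl3 (-2.49 ± 0.16) and Ccl12 (-2.44 ± 0.33). Inflammatory genes moved both ways, as 10 rose and 13 fell (10 and 14 over the list alone) of 37 (median -0.010, lower by camera with adjusted p = 0.00540, but 0.433 with an estimated correlation; the median is above 0 with RLE scaling). Tnf (-2.26 ± 0.14) and Ccl22 (-2.24 ± 0.40) were among those that fell. Interferon-response genes had 0 higher and 11 lower (0 and 16 over the list alone) of 47 (adjusted p = 5.36e-07, but 0.285 with an estimated correlation). Examples are Cxcl9 (-1.98 ± 0.22) and Irf1 (-1.25 ± 0.16). The NRF2 list had 4 higher and 0 lower (4 and 0 over the list alone) of 20 (adjusted p = 0.0150, but 0.285 with an estimated correlation) and the translation list 3 higher and 0 lower (0 and 0 over the list alone) of 47 (adjusted p = 0.00165, but 0.515 with an estimated correlation). pGE2 changed 555 of 4963 genes, 258 higher and 297 lower. Of these, 555 had one sign on both plates. Counts were 371 on plate 1 alone, 253 on plate 2 alone and 506 with same-named wells summed, 462 of these shared.

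In Baflo and ZVAD wells no single gene passed. For Baflo, edgeR called 0 of 4963 genes, with 373 at an unadjusted p under 0.05 (DESeq2 called 0, and edgeR called 0 with same-named wells summed, 0 on plate 1, 0 on plate 2, 3 with no filter on low counts and 8 with only the compared groups in the fit). Lysosome and autophagy genes, expected for this label, had a median of 0.083 with no member past the threshold and no call (adjusted p = 0.107), but were called with same-named wells summed (0.13, adjusted p = 0.0195). Lamp1 was at 0.12 ± 0.11, Lamp2 at -0.074 ± 0.14 and Ctsa at 0.23 ± 0.12. The sterol synthesis gene Hmgcs1 (-0.32 ± 0.37) did not pass. The inflammatory list was higher as a list with 0 of 37 members past the threshold (2 and 0 over the list alone; adjusted p = 5.41e-05, but 0.267 with an estimated correlation). So was the translation list with 0 of 47 (1 and 0 over the list alone; adjusted p = 1.81e-07, but 0.285 with an estimated correlation). For ZVAD, edgeR called 0 genes, with 176 at an unadjusted p under 0.05 (DESeq2 called 0, and edgeR called 0 with same-named wells summed, 0 on plate 1 and 0 on plate 2). ZVAD wells had Tnf at -0.055 ± 0.12, Il1a at -0.022 ± 0.26, Il1b at 0.035 ± 0.13, Ifit1 at -0.16 ± 0.14 and Ifit2 at -0.081 ± 0.18. Of the ZVAD lists the translation list alone was called, with 0 of 47 members past the threshold (0 and 0 over the list alone; adjusted p = 0.0179, but 0.632 with an estimated correlation). The inflammatory (adjusted p = 0.404) and interferon lists (adjusted p = 0.183) were not called.

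Caspase-1 wells (the label of a compound, not a measurement of the enzyme) had changes in a mixed set of genes. Cap1, an actin regulator gene (ENSMUSG00000028656.14, chromosome 4, 122859047 to 122886056; -2.65 ± 0.44, adjusted p = 5.85e-05), Rbm45, an RNA-binding protein gene (-1.72 ± 0.31, adjusted p = 0.000418), and Soat1, a cholesterol esterification gene (-1.20 ± 0.17, adjusted p = 2.05e-07), fell. Cacna1a (-1.18 ± 0.35), Nmrk1 (-1.14 ± 0.34) and Rnf11 (-1.13 ± 0.28) fell with adjusted p up to 0.0426. The highest were Rrs1 (1.24 ± 0.34), Mxd3 (1.03 ± 0.30), Hnrnpul2 (0.95 ± 0.28), Rgl1 (0.94 ± 0.26), Sptlc2 (0.93 ± 0.26) and Ndufc1 (0.92 ± 0.26), with adjusted p up to 0.0397. Inflammatory genes had 5 higher and 1 lower (10 and 4 over the list alone) of 37 (camera adjusted p = 0.0190, but 0.510 with an estimated correlation). Ccl7 (0.76 ± 0.16), Bcl3 (0.75 ± 0.20) and Ccl2 (0.61 ± 0.16) rose, and Tnf (-0.033 ± 0.12), Il1a (-0.13 ± 0.26) and Il1b (0.24 ± 0.13) did not pass. Interferon genes Ifit1 (-0.11 ± 0.14) and Ifit2 (-0.0063 ± 0.18) did not pass, and Ifi44 fell (-0.54 ± 0.16, adjusted p = 0.0397). Translation genes had 8 higher and 1 lower (20 and 1 over the list alone) of 47 (adjusted p = 1.27e-10, but 0.177 with an estimated correlation). One example is Rpl5 (0.67 ± 0.12). Lysosome genes had 3 higher and 0 lower (3 and 0 over the list alone) of 34 (adjusted p = 0.0314, but 0.327 with an estimated correlation) and heat shock genes 1 higher and 0 lower (1 and 0 over the list alone) of 14 (adjusted p = 0.0421, but 0.0877 with an estimated correlation). The Rn45s share was 4.07 percentage points below that of DMSO wells (exact permutation p = 0.0897, adjusted p = 0.493). Caspase-1 changed 144 of 4963 genes, 69 higher and 75 lower. Of these, 144 had one sign on both plates. Counts were 194 on plate 1 alone, 3 on plate 2 alone and 62 with same-named wells summed, 56 of these shared. The count ranged from 17 to 71 with a well letter left out and was 77 with the Rn45s share as a covariate, 274 with DESeq2 and 350 with only the compared groups in the fit. RLE scaling gave 89 higher and 61 lower (59.3% higher in place of 47.9%), and Cap1, Rbm45, Soat1, Rnf11, Ccl7 and Rpl5 were past the threshold with summed wells and with the covariate. Mxd3, Sptlc2, Ndufc1, Cacna1a and Ifi44 were so with neither, Hnrnpul2, Rgl1 and Nmrk1 not with summed wells, and Rrs1, Bcl3 and Ccl2 not with the covariate.

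Halofuginone wells had higher transcripts of the cyclic AMP list and lower transcripts of the translation machinery list. Egr1 (ENSMUSG00000038418.7, chromosome 18, 34859823 to 34864984; 5.88 ± 0.34, adjusted p = 9.08e-27), Nr4a1 (5.77 ± 0.49), Ier2 (4.72 ± 0.27) and Jun (4.45 ± 0.26), immediate early genes, rose most, with the histone gene Hist1h4m (5.73 ± 0.46) and Gdf15 (4.67 ± 0.34). The cyclic AMP list had 8 higher and 2 lower (8 and 2 over the list alone) of 13. The median was 1.70 (camera adjusted p = 6.73e-07, and 0.000620 with an estimated correlation). Fos (3.89 ± 0.29) and Rgs2 (3.17 ± 0.20) were among those that rose. The p53 list had 6 higher and 2 lower (6 and 3 over the list alone) of 12 (adjusted p = 0.00572, and 0.0272 with an estimated correlation). Among these were the antiproliferative gene Btg2 (3.69 ± 0.31), Plk2 (3.27 ± 0.24) and the proapoptotic gene Bbc3 (2.96 ± 0.36). Translation machinery genes had 1 higher and 41 lower (2 and 43 over the list alone) of 47. The median was -1.26 (adjusted p = 7.32e-19, and 0.0392 with an estimated correlation). Examples are Rpl23 (-1.71 ± 0.14), Rpl18 (-1.66 ± 0.19) and Rps14 (-1.59 ± 0.15). These groups moved in libraries with the lowest totals and the highest Rn45s share, and the median of all tested genes was -0.20. The genes with the lowest fitted fold changes had almost no counts in Halofuginone wells: Ppargc1b (1 against 116 counts, log2 ratio -4.94, 95% counting interval -10.26 to -2.44), Batf2 (1 against 83 counts, log2 ratio -4.46, 95% counting interval -9.78 to -1.94) and Ndufs3 (1 against 76 counts, log2 ratio -4.33, 95% counting interval -9.66 to -1.81). Spsb1, Blvra and Pla2g16 had 2 counts each against 112, 96 and 96. Fitted fold changes of such genes depend on the prior count, and the intervals cover counting error alone.

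The ATF4 list, expected for Halofuginone, had 5 higher and 2 lower (6 and 2 over the list alone) of 17 and no call (median -0.058, mean 0.36, adjusted p = 0.122; with the Rn45s share as a covariate it was called). Ppp1r15a, which promotes dephosphorylation of a translation factor (3.81 ± 0.30), the stress transcription factor genes Ddit3 (2.25 ± 0.39), Atf3 (1.17 ± 0.16) and Atf4 (0.91 ± 0.19) rose, and the folate enzyme gene Mthfd2 fell (-2.06 ± 0.61, adjusted p = 0.00418). Of the tRNA synthetase genes, 1 rose and 0 fell (1 and 0 over the list alone) of 15 with no call (adjusted p = 0.933): Mars rose (2.09 ± 0.47), and Aars (-0.48 ± 0.45), Cars (-0.20 ± 0.53) and Eprs (-0.029 ± 0.19) did not pass. Interferon-response genes had 4 higher and 29 lower (4 and 29 over the list alone) of 47 (adjusted p = 0.00219, but 0.510 with an estimated correlation). Examples are Cmpk2 (-2.58 ± 0.23) and Rsad2 (-2.35 ± 0.19). Inflammatory genes had 14 higher and 11 lower (15 and 12 over the list alone) of 37 and no call (adjusted p = 0.162). The chemokine gene Cxcl2 rose (2.45 ± 0.20), and Il6 (-2.74 ± 0.47) and Il1b (-2.32 ± 0.15) fell. The NRF2 list had 1 higher and 10 lower (2 and 12 over the list alone) of 20 (adjusted p = 0.0268, but 0.336 with an estimated correlation) and the glucocorticoid-induced list 3 higher and 2 lower (4 and 2 over the list alone) of 13 (adjusted p = 0.0432, but 0.214 with an estimated correlation). Halofuginone changed 2000 of 4963 genes, 760 higher and 1240 lower. Of these, 1997 had one sign on both plates. Counts were 1302 on plate 1 alone, 1195 on plate 2 alone and 2064 with same-named wells summed, 1843 of these shared. With Halofuginone and DMSO libraries thinned to one total, a mean of 51.9% of the genes past the threshold were higher, in place of 38.0% (43.3% in the same fit unthinned), so the excess of lower genes depends on depth. With the Rn45s share as a covariate 1141 genes passed, 1056 of them shared.

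BrefA wells had higher transcripts of the unfolded protein response and ATF4 lists and lower transcripts of the interferon list. Gdf15 (4.20 ± 0.31), Herpud1, an endoplasmic reticulum degradation gene (ENSMUSG00000031770.16, chromosome 8, 94386438 to 94395377; 3.72 ± 0.25, adjusted p = 3.86e-27), Ddit3 (3.15 ± 0.28), the amino acid transporter gene Slc38a2 (3.04 ± 0.21), the cytokine subunit gene Il23a (2.99 ± 0.37) and Mars (2.82 ± 0.33) rose most. Of 28 unfolded protein response genes 18 rose and 0 fell (20 and 0 over the list alone). The median was 0.71 (camera adjusted p = 1.14e-13, and 3.37e-09 with an estimated correlation). The chaperone genes Hspa5 (1.66 ± 0.11), Dnajb9 (2.16 ± 0.30), Hsp90b1 (0.87 ± 0.17) and Pdia6 (1.53 ± 0.24) rose, and Pdia3 did not pass (0.53 ± 0.24). The ATF4 list had 12 higher and 1 lower (14 and 1 over the list alone) of 17. Its median was 1.39 (adjusted p = 9.17e-14, and 7.72e-08 with an estimated correlation). Atf4 (2.58 ± 0.15) and the asparagine synthetase gene Asns (2.39 ± 0.37) rose and Atf3 fell (-1.04 ± 0.16). Of 15 tRNA synthetase genes 9 rose and 0 fell (9 and 0 over the list alone) (adjusted p = 1.48e-06, and 3.46e-05 with an estimated correlation). Among these were Cars (1.77 ± 0.28) and Tars (1.44 ± 0.30). Of 47 interferon-response genes 0 rose and 37 fell (0 and 39 over the list alone). Their median was -1.52 (adjusted p = 2.50e-43, and 0.000257 with an estimated correlation). Mx1 (-2.50 ± 0.20) and Cmpk2 (-2.41 ± 0.20) were among them. Socs1 (-4.07 ± 0.30), the interferon-inducible GTPase genes Iigp1 (-4.04 ± 0.25), Tgtp1 (-3.20 ± 0.25) and Tgtp2 (-3.19 ± 0.26), the ceruloplasmin gene Cp (-3.14 ± 0.24) and Batf2 (-2.94 ± 0.43) fell most. Inflammatory genes moved both ways, with 12 higher and 6 lower (13 and 6 over the list alone) of 37 (adjusted p = 0.00593, but 0.435 with an estimated correlation). The chemokine genes Cxcl1 (2.31 ± 0.18) and Cxcl2 (2.10 ± 0.19) rose. The p53 list had 4 higher and 0 lower (4 and 0 over the list alone) of 12, with a median of -0.042, a mean of 0.56 and a test result for higher (adjusted p = 0.0144, but 0.0547 with an estimated correlation). The macrophage identity list had 0 higher and 7 lower (0 and 7 over the list alone) of 22 (adjusted p = 0.00583, but 0.0887 with an estimated correlation). BrefA changed 860 of 4963 genes, 401 higher and 459 lower. Of these, 857 had one sign on both plates. Counts were 518 on plate 1 alone, 487 on plate 2 alone and 783 with same-named wells summed, 701 of these shared.

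Tunicamycin wells had higher transcripts of the ATF4 list. Herpud1 (2.15 ± 0.28, adjusted p = 4.72e-09), Trappc11, a vesicle transport gene (2.08 ± 0.50), Ddit3 (1.54 ± 0.33), Saa3 (1.52 ± 0.17), Atf4 (ENSMUSG00000042406.8, chromosome 15, 80255184 to 80257541; 1.5 ± 0.16) and Ptges, a prostaglandin synthesis gene (1.48 ± 0.29), rose most. Rbm45 (-1.46 ± 0.31), Irf8 (-1.40 ± 0.14), the chemokine gene Cxcl9 (-1.20 ± 0.20), Socs1 (-1.12 ± 0.21), Taf7 (-1.10 ± 0.31, adjusted p = 0.0210) and Slfn9 (-1.08 ± 0.31, adjusted p = 0.0294) fell most. The ATF4 list had 3 higher and 0 lower (6 and 0 over the list alone) of 17 (camera adjusted p = 2.82e-06, and 0.000587 with an estimated correlation), while Atf3 did not pass (-0.14 ± 0.15). Its median was 0.48, but 0.81 (adjusted p = 5.20e-06) on plate 1 alone and 0.21 (adjusted p = 0.0151) on plate 2 alone. Of 28 unfolded protein response genes 2 rose and 0 fell (3 and 0 over the list alone), with no call for the list (adjusted p = 0.208). Hspa5 rose (0.53 ± 0.11) and Hsp90b1 (0.12 ± 0.18) and Pdia3 (-0.15 ± 0.26) did not pass. Herpud1 is a member of both this list and the ATF4 list. The inflammatory list had 8 higher and 1 lower (16 and 4 over the list alone) of 37 (adjusted p = 3.36e-05, but 0.253 with an estimated correlation). One example is the chemokine gene Cxcl3 (1.45 ± 0.21). The interferon list had 0 higher and 8 lower (1 and 9 over the list alone) of 47 (adjusted p = 3.19e-09, but 0.207 with an estimated correlation). One example is Iigp1 (-0.94 ± 0.20). The translation list had 10 higher and 0 lower (28 and 0 over the list alone) of 47 (adjusted p = 5.39e-13, but 0.115 with an estimated correlation). One example is Rps18 (0.51 ± 0.13). The hypoxia and glycolysis list had 4 higher and 0 lower (6 and 0 over the list alone) of 19 (adjusted p = 0.00583, but 0.0960 with an estimated correlation). On plate 2 alone the inflammatory (0.11, adjusted p = 0.170, against a median of 0.48 on plate 1) and hypoxia lists (0.052, adjusted p = 0.395, against 0.31) were not called. Tunicamycin changed 217 of 4963 genes, 139 higher and 78 lower. Of these, 213 had one sign on both plates. Counts were 378 on plate 1 alone, 5 on plate 2 alone and 110 with same-named wells summed, 106 of these shared. Without library Tunicamycin plate 2 F, 238 genes passed (181 shared), and the ATF4 list had median 0.53, adjusted p = 7.07e-07. Then the interferon list had median -0.15, adjusted p = 0.0114 (in place of -0.28; Iigp1 -0.78), the inflammatory list median 0.44, adjusted p = 2.14e-07 and the unfolded protein response list median 0.063, adjusted p = 0.177. DESeq2 called 296 genes, and a fit of the compared groups alone 112. Trappc11, Slfn9 and Rps18 were not past the threshold with summed wells.

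**Figure D3:**
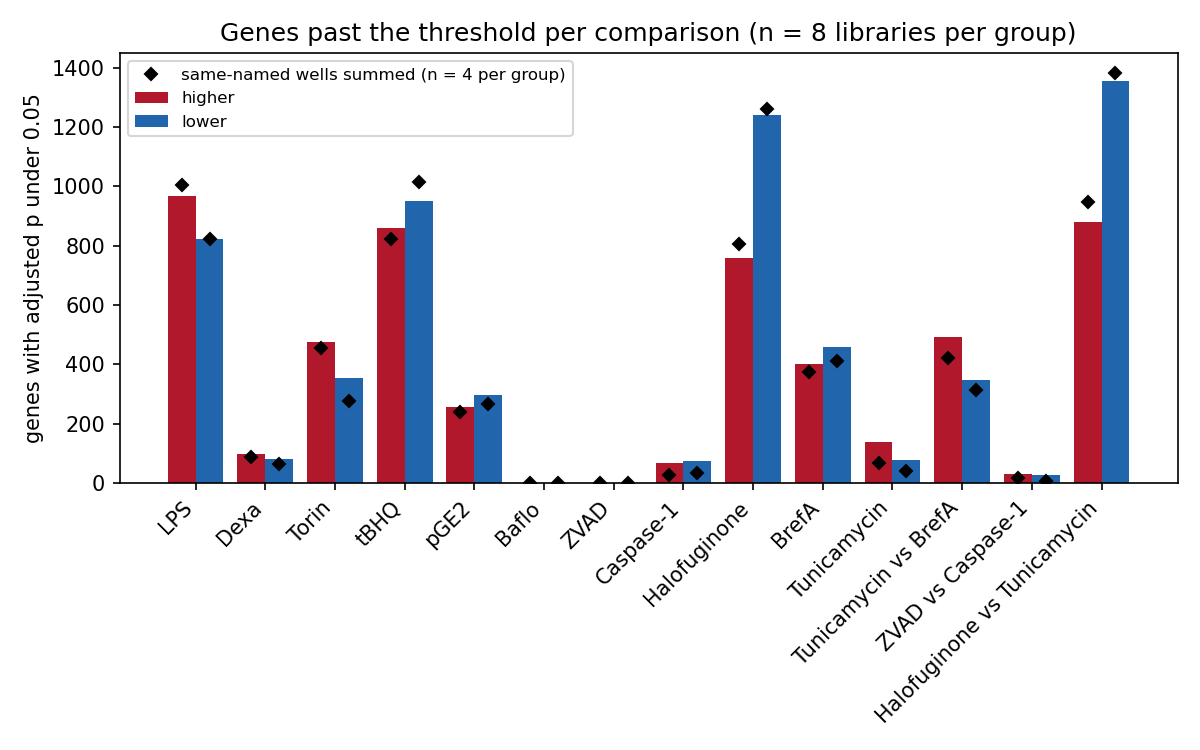
Number of genes with adjusted p under 0.05 in each comparison, higher (red bars) and lower (blue bars), from edgeR with 8 libraries per group, with diamonds for the counts when same-named wells are summed to 4 per group. Halofuginone, tBHQ and LPS have the most among the comparisons with DMSO or NoStim (2000, 1807 and 1790 genes), and Baflo and ZVAD have 0 each.

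Some compounds with related expected lists were also compared with each other. Tunicamycin wells had lower transcripts of the unfolded protein response and ATF4 lists than BrefA wells and higher transcripts of the interferon list. Of 28 unfolded protein response genes 0 rose and 15 fell (0 and 21 over the list alone). The median was -0.66 (camera adjusted p = 2.94e-12, and 8.53e-09 with an estimated correlation). Examples are Dnajb9 (-2.39 ± 0.31), Herpud1 (-1.57 ± 0.20) and Hspa5 (-1.13 ± 0.10). The ATF4 list had 1 higher and 9 lower (1 and 11 over the list alone) of 17 (adjusted p = 4.55e-07, and 0.000221 with an estimated correlation). One example is Ddit3 (-1.62 ± 0.24). The tRNA synthetases had 0 higher and 6 lower (0 and 8 over the list alone) of 15 (adjusted p = 2.97e-05, and 0.000264 with an estimated correlation). One example is Mars (-1.49 ± 0.28). Of 47 interferon-response genes 36 rose and 0 fell (38 and 0 over the list alone). Their median was 1.22 (adjusted p = 6.14e-28, and 0.00532 with an estimated correlation). Examples are Iigp1 (3.10 ± 0.26) and Mx1 (2.11 ± 0.20). Saa3 (3.31 ± 0.20), Cp (3.0 ± 0.24) and Socs1 (2.95 ± 0.34) were also higher, and Gdf15 (-3.31 ± 0.28), Il12b (-2.92 ± 0.16) and Klf9 (-2.59 ± 0.41) lower. The macrophage identity list had 9 higher and 0 lower (9 and 0 over the list alone) of 22 (adjusted p = 0.00128, and 0.0384 with an estimated correlation). Calls were lost with an estimated correlation for the translation list (16 higher and 0 lower (28 and 0 over the list alone); adjusted p = 2.97e-05, then adjusted p = 0.396), the glucocorticoid-induced list (7 higher and 1 lower (7 and 2 over the list alone); adjusted p = 0.0164, then adjusted p = 0.116) and the p53 list (1 higher and 4 lower (1 and 4 over the list alone); adjusted p = 0.0339, then adjusted p = 0.106). On plate 2 alone the glucocorticoid-induced list had the other sign (-0.090, adjusted p = 0.785, against 0.94 on plate 1), and it, the translation (0.083, adjusted p = 0.484, against 0.46) and the p53 list were not called, nor was the p53 list on plate 1 or with summed wells. Tunicamycin against BrefA changed 840 of 4963 genes, 493 higher and 347 lower. Of these, 813 had one sign on both plates. Counts were 1029 on plate 1 alone, 373 on plate 2 alone and 736 with same-named wells summed, 682 of these shared. Without Tunicamycin plate 2 F 908 genes passed, 789 of them shared, and the interferon list had median 1.32, adjusted p = 4.20e-41. A fit of these groups alone called 548 genes.

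Few genes passed between ZVAD and Caspase-1 wells, and chance cannot be excluded (2 of 35 splits of these wells, fitted alone, gave 154 genes or more, the real one included). Cap1 (2.34 ± 0.44, adjusted p = 0.00129), the splicing-related genes Ddx23 (1.61 ± 0.45, adjusted p = 0.0492) and Srek1 (1.34 ± 0.26, adjusted p = 0.00129) and Brd8 (1.38 ± 0.33, adjusted p = 0.0167) were higher. Srp54a (-0.83 ± 0.23), Mff (-0.81 ± 0.22), Eif3g (-0.76 ± 0.21), Atp1b3 (-0.70 ± 0.16) and Rpl5 (-0.63 ± 0.12) were lower, with adjusted p up to 0.0452. The translation list had 1 higher and 1 lower (1 and 6 over the list alone) of 47 (camera adjusted p = 2.41e-07, but 0.285 with an estimated correlation) and the lysosome list 0 higher and 1 lower (0 and 5 over the list alone) of 34 (adjusted p = 0.0421, but 0.360 with an estimated correlation). ZVAD against Caspase-1 changed 58 of 4963 genes, 30 higher and 28 lower. Of these, 58 had one sign on both plates. Counts were 146 on plate 1 alone, 0 on plate 2 alone and 24 with same-named wells summed, 21 of these shared. The count was 2 to 18 with a well letter left out, 10 without the plate term, 23 with the Rn45s share as a covariate, 112 with DESeq2 and 154 in a fit of these groups alone.

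Halofuginone wells had higher transcripts of the cyclic AMP list and lower transcripts of the translation list than Tunicamycin wells too, again with the lower totals and higher Rn45s share of Halofuginone libraries and a median of all tested genes of -0.19. Egr1 (5.93 ± 0.34, adjusted p = 8.96e-27), Jun (4.96 ± 0.27) and Nr4a1 (4.85 ± 0.44) were higher (7.33, 5.43 and 5.93 without Tunicamycin plate 2 F), and Hist1h4m (85 against 2 counts, log2 ratio 7.33, 95% counting interval 5.43 to 10.40) and Ier5l (66 against 3 counts, log2 ratio 6.38, 95% counting interval 4.77 to 8.69) had few counts in Tunicamycin wells. The cyclic AMP list had 8 higher and 3 lower (8 and 3 over the list alone) of 13 (camera adjusted p = 0.000144, and 0.0123 with an estimated correlation). The translation list had 1 higher and 44 lower (2 and 44 over the list alone) of 47. The median was -1.56 (adjusted p = 4.15e-24, and 0.0164 with an estimated correlation). Examples are Rpl32 (-2.09 ± 0.18) and Rps23 (-2.00 ± 0.15). Herpud1 was lower (-3.37 ± 0.51), and Ppargc1b (1 against 119 counts), Ndufs3 (1 against 74), Polr2c (1 against 72) and Pla2g16 (2 against 98) had the lowest fitted fold changes. The NRF2 list had 2 higher and 11 lower (2 and 11 over the list alone) of 20 (adjusted p = 0.0179, but 0.296 with an estimated correlation) and the p53 list 6 higher and 3 lower (6 and 3 over the list alone) of 12 (adjusted p = 0.0183, but 0.0703 with an estimated correlation). The interferon list was not called (adjusted p = 0.320), but was without Tunicamycin plate 2 F (median -0.71, adjusted p = 0.00846). Halofuginone against Tunicamycin changed 2234 of 4963 genes, 880 higher and 1354 lower. Of these, 2210 had one sign on both plates. Counts were 1614 on plate 1 alone, 1365 on plate 2 alone and 2327 with same-named wells summed, 2074 of these shared. Totals were not made equal for this split. The Rn45s share as a covariate left 1017 genes past the threshold, and a fit of these groups alone 1152.

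**Figure D4:**
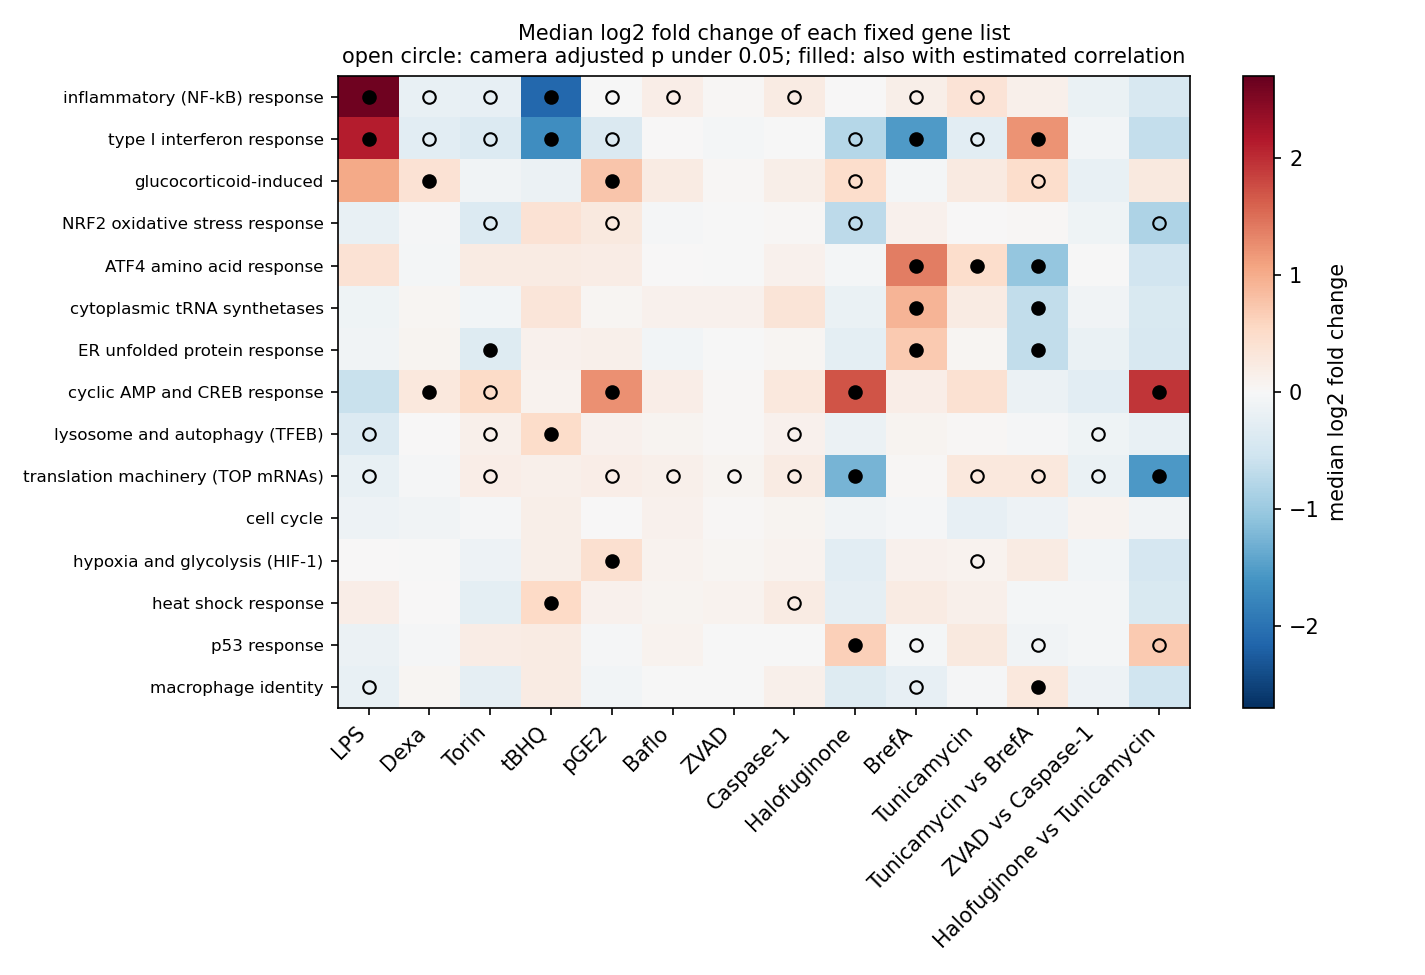
Median log2 fold change (colour) of each fixed gene list with at least 5 tested members (rows) in each comparison (columns). Open circles mark a camera adjusted p under 0.05 and filled circles a call that holds with an estimated correlation as well, which is so for 27 of 66 calls.

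To ask how each compound bore on the LPS response as a whole, genes that LPS changed past the threshold and at least 2-fold were called on each plate, and the compound's fold change was measured on the other (602 induced and 402 repressed genes called on plate 1, 586 and 342 of them tested on plate 2, and 437 and 216 called on plate 2, 435 and 209 of them tested on plate 1). LPS-induced genes had their lowest median in tBHQ wells (-1.41 ± 0.19, SD of n = 8 wells). Those of Halofuginone (-0.55 ± 0.15), BrefA (-0.41 ± 0.056), pGE2 (-0.27 ± 0.032), Torin (-0.22 ± 0.065) and Dexa (-0.16 ± 0.058) were also below 0, and each was so in 8 of 8 wells, as for tBHQ. The Halofuginone median was -0.33 on plate 2 and -0.76 on plate 1, against -0.36 and -0.47 for BrefA, and all tested genes had a median of -0.20 in Halofuginone wells. Medians of Baflo (0.055 ± 0.050), ZVAD (-0.015 ± 0.060), Caspase-1 (0.069 ± 0.064) and Tunicamycin wells (-0.012 ± 0.23) did not have one sign in 8 of 8 wells. Library Tunicamycin plate 2 F had -0.59, and without it the Tunicamycin median was 0.053 ± 0.048, with 6 of 7 wells above 0. LPS-repressed genes were above 0 in 8 of 8 wells for tBHQ (0.98 ± 0.10), Torin (0.39 ± 0.10), BrefA (0.12 ± 0.053), Dexa (0.099 ± 0.048) and pGE2 (0.061 ± 0.032), but not for Halofuginone (0.16 ± 0.32). These medians carry no p-value. Wells of a plate share a DMSO mean, so their signs are not independent and their SD omits its spread. Same-named DMSO wells may share a lysate, which would push medians away from 0. With DMSO letters split between the LPS and the compound contrast instead, induced genes had medians of -1.39 (E and F for LPS) and -1.43 (G and H) for tBHQ, -0.48 and -0.56 for Halofuginone, -0.38 and -0.43 for BrefA, -0.25 and -0.24 for pGE2, -0.23 and -0.21 for Torin and -0.15 and -0.14 for Dexa.

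**Figure D5:**
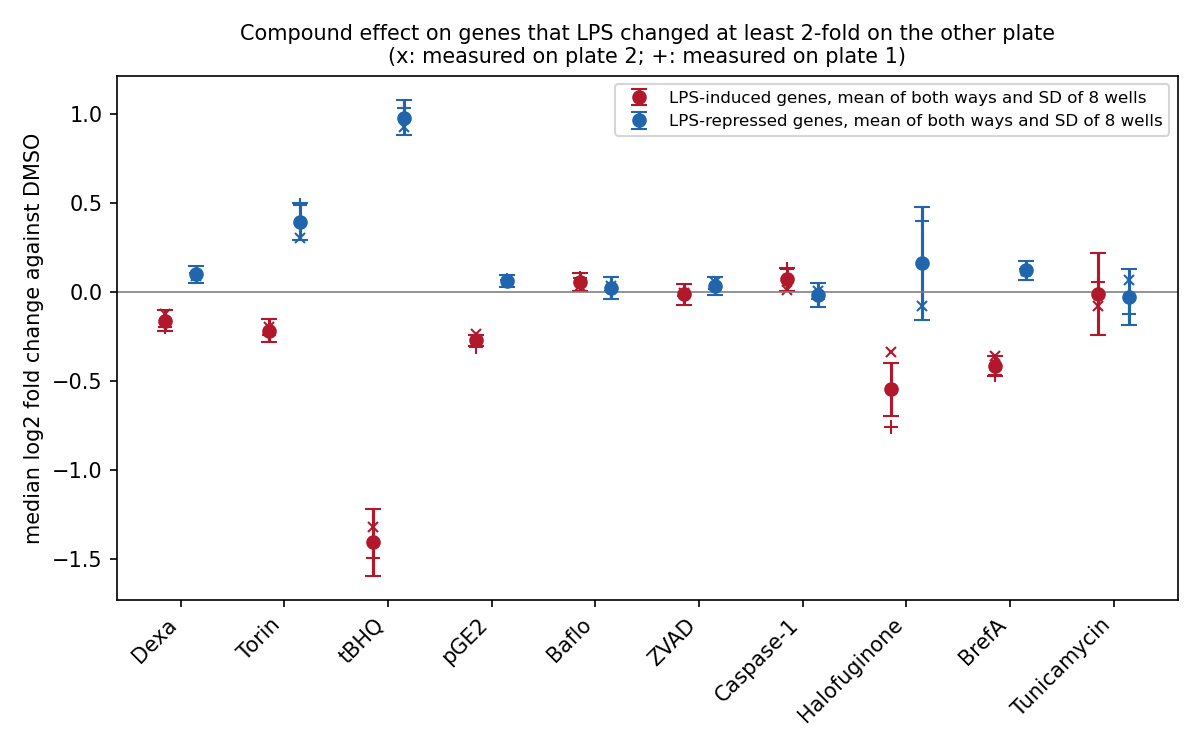
Median log2 fold change against DMSO of LPS-induced (red) and LPS-repressed (blue) genes in each compound's wells, with circles for the mean of both ways of calling and measuring, bars for the SD of 8 wells, crosses for values measured on plate 2 and plus signs for plate 1. The tBHQ medians lie farthest from 0 (-1.41 and 0.98).

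Fold changes of each compound on one plate were correlated across 4963 genes with those on the other, and genes are not independent replicates. Same-named wells may share a lysate, so the plates need not be independent. Values with 2 letters on one plate against the other 2 on the other plate (mean of 6 ways, fewer wells, no letter shared) therefore follow each r. A compound's own profile recurred most for tBHQ (r = 0.851, 0.727 with other letters), BrefA (0.677, 0.506), pGE2 (0.658, 0.460) and Torin (0.657, 0.474), and less for Dexa (0.420, 0.192), Caspase-1 (0.290, 0.146), Tunicamycin (0.216, 0.113) and Baflo (0.126, 0.0600). For ZVAD r was 0.0895, but 0.00858 with other letters, within the 0.0300 that 20 simulations with unchanged groups reached. Halofuginone had 0.728, 0.557, but its libraries simulated as unchanged gave up to 0.432 and 0.270, against at most 0.0608 and 0.0300 in the other groups. The simulations drew genes independently, so chance may reach higher r. Unlike in the data, their prior count of 2 was not scaled to library size. The simulated Halofuginone values therefore cannot be put down to low depth alone. Between compounds r was highest for tBHQ and BrefA (0.341, 0.277 with other letters). Next were BrefA and Tunicamycin (0.281, 0.167, but 0.197 on all letters without Tunicamycin plate 2 F, below the pairs that follow), Torin and BrefA (0.258, 0.187), Torin and Halofuginone (0.247, 0.180), Torin and tBHQ (0.231, 0.183), Halofuginone and BrefA (0.229, 0.169) and tBHQ and pGE2 (0.223, 0.174). Simulations with other letters, under the same limit, reached at most 0.0537 in size. In the same order, covariances with other letters were 0.143, 0.0568, 0.0734, 0.115, 0.0912, 0.111 and 0.0795 (simulated mean -0.000418).

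The remaining lists bear on cell identity and RNA quality. Of 11 tested cell cycle genes the list was called in none of the 14 comparisons, by camera with either correlation. Markers of other cell types were low beside the macrophage gene Lyz2 (mean 346 CPM): the highest were Blnk for B cells (96.2, a gene macrophages also express), Cxcr2 for neutrophils (31.1), Cd74 for dendritic cells (29.4), Lck for T and NK cells (5.01), Sparc for fibroblasts (2.19) and Alas2 for erythroid and mast cells (0.193). Blnk, looked up by group after its values were seen, was at 67.4 CPM in DMSO wells and past the threshold against these in Torin (165), BrefA (127), NoStim (114) and tBHQ wells (103). None of the mitochondrially encoded genes is in the table, so that list gave no value. Of 4 tested sterol synthesis genes 2 rose and 1 fell with LPS (2 and 1 over the list alone).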

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

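The test of tBHQ wells for missing LPS, the directions of calls in thinned Halofuginone libraries, the Rn45s covariates and the fits without named wells were chosen only after the result was seen.

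Values of single libraries lay far from the other 7 of their group in 39 of 525 checks (7.43%), where chance gives about 1 in 20. Each had a gap to the nearest library, as a share of the group's range, above Dixon's 95% critical value for 8 values. The share, the library and the mean of the others follow, in log2 CPM for genes. In DMSO wells these were the Rn45s percentage (0.587; plate 1 G at 9.43 against 20.8), the mean of the lysosome list (0.530; plate 1 G at 7.24 against 7.36), Il12b (0.550; plate 1 G at 8.54 against 8.07), Slc26a11 (0.532; plate 1 E at 4.20 against 3.19), Lamp1 (0.534; plate 1 E at 8.07 against 8.57), Rps20 (0.753; plate 1 G at 9.43 against 8.82), Procr (0.535; plate 1 H at 6.12 against 4.84), Ifi44 (0.5261; plate 2 G at 7.21 against 7.97), Rgs2 (0.765; plate 2 G at 5.74 against 6.20) and Taf7 (0.590; plate 2 F at 3.95 against 5.62). In Tunicamycin wells these were the total count (0.623; plate 2 H at 360200 against 242450), the number of genes detected (0.528; plate 2 H at 9852 against 9246), Socs1 (0.669; plate 2 F at 3.65 against 6.47), Iigp1 (0.784; plate 2 F at 5.67 against 8.87), Mx1 (0.731; plate 2 F at 6.56 against 8.78), Egr1 (0.603; plate 2 F at 7.15 against 3.88) and Nr4a1 (0.554; plate 2 F at 5.37 against 3.33). In Dexa wells this was Tnf (0.636; plate 2 H at 10.32 against 9.87). In Torin wells this was Lipg (0.569; plate 2 G at 5.03 against 5.63). In tBHQ wells this was Il1b (0.604; plate 2 F at 6.41 against 7.95). In pGE2 wells this was Ddit4 (0.591; plate 2 G at 5.80 against 6.45). In ZVAD wells these were Tnf (0.570; plate 2 G at 10.46 against 10.02), Ifit2 (0.567; plate 2 G at 9.61 against 10.27) and Srp54a (0.556; plate 2 F at 4.71 against 5.51). In Caspase-1 wells these were Ndufc1 (0.569; plate 1 H at 6.49 against 5.80), Cacna1a (0.618; plate 2 H at 2.95 against 4.47), Bcl3 (0.557; plate 2 F at 6.79 against 7.85), Ccl2 (0.712; plate 2 F at 9.65 against 10.27), Ifi44 (0.565; plate 1 E at 6.87 against 7.43) and Atp1b3 (0.567; plate 2 F at 6.79 against 7.62). In Halofuginone wells these were Hist1h4m (0.733; plate 2 F at 6.25 against 7.42), Ppargc1b (1; plate 1 F at 4.36 against 2.95), Batf2 (1; plate 1 F at 4.36 against 2.95), Ndufs3 (1; plate 1 E at 4.58 against 2.95), Mars (0.699; plate 2 F at 2.95 against 5.99), Rpl18 (0.601; plate 2 G at 4.26 against 7.12) and Polr2c (1; plate 2 H at 4.64 against 2.95). In BrefA wells these were Iigp1 (0.637; plate 1 E at 3.58 against 5.89) and Cxcl2 (0.544; plate 2 H at 11.40 against 12.24). The shares of 1 in Halofuginone wells are genes with a count in a single library.

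The change differed between plates, by a test of the plate by treatment interaction in edgeR, for 27 genes in Caspase-1 wells, with the lowest p for Gnb1 (1.02, adjusted p = 0.0101). It differed for 2 genes in BrefA wells, Cxcl10 (0.83, adjusted p = 0.00751) and Car13, and for 2 in Tunicamycin wells, Stap1 (1.94, adjusted p = 0.0301) and Fcgr2b. It differed for 36 genes between Tunicamycin and BrefA, with the lowest p for Btbd19 (1.88, adjusted p = 0.0288), and for 12 between ZVAD and Caspase-1, with the lowest p for Gm12250 (-1.05, adjusted p = 0.00860). Without Tunicamycin plate 2 F, edgeR gave 0 genes for Tunicamycin (384 at an unadjusted p under 0.05) and 45 between Tunicamycin and BrefA.

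The 144 genes called in Caspase-1 wells rest on libraries whose mean Rn45s share was below that of DMSO wells. With the share as a covariate the called genes kept a median of 0.922 of their log2 fold change (0.895 to 0.927 with a letter left out), which argues against the share as the whole cause, while 67 of them stayed past the threshold. The share stays related to them: 122 of 144 have the sign its slope gives, and fold changes and slopes have r = -0.619. Wells of the same name counted on both plates stay open as part of the count, since 62 genes passed with these wells summed and 7 to 22 when a letter was left out as well (lowest without G). An effect of the compound is the biological alternative and was not tested apart from these.

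Lower translation machinery transcripts in Halofuginone wells came with low totals and high Rn45s share. Thinned to a total of 80196 with Rn45s, 10 draws gave a list median of -1.09 (SD 0.028) against -1.26 unthinned. Thinning keeps expected gene shares, so this argues against unequal totals alone, not against what made them low. Of all genes 1372 to 1441 passed, 50.6% to 53.2% higher, against 1916 with 43.3% higher unthinned, so the excess of lower genes went with unequal totals. Slopes on the Rn45s share within groups predict a median of -0.40 (-0.41 to -0.36 with a letter left out), so part of the change cannot be told apart from the share. No other group reaches the Halofuginone share, so the slopes are extrapolated.

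The LPS response was lower in tBHQ wells. With the Rn45s share as a covariate the inflammatory median was -2.12 (-2.16 to -1.96 with a letter left out), which argues against the share. Wells that got no LPS would match NoStim wells, and against these tBHQ wells had an inflammatory median of 0.36 (0.18 to 0.61 with a letter left out), with 16 of 37 genes higher and 0 lower (adjusted p = 1.15e-15, and 0.00393 with an estimated correlation). This argues against wells alike with NoStim wells, but no compound was given without LPS, so genes raised by the compound itself would look the same. The median meets the 0.3 set as the bound against missing LPS, but its range reaches below. Missing LPS is therefore not excluded, and weak or partial LPS was not tested. Hmox1, which the compound is expected to raise with or without LPS, was higher than in NoStim wells (2.00, adjusted p = 1.57e-21), one of 412 genes past the threshold.

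Each count was set against 35 splits of the 8 well letters of the compared groups, fitted alone, the real split included. The counts argue against chance where 1 of 35 splits, the real one, gave as many genes: LPS (1479 genes, highest other 145), Dexa (197 genes, highest other 13), Torin (849 genes, highest other 3), tBHQ (1515 genes, highest other 393), pGE2 (705 genes, highest other 42), Caspase-1 (350 genes, highest other 215), Halofuginone (1181 genes, highest other 1), BrefA (806 genes, highest other 6), Tunicamycin (112 genes, highest other 20), Tunicamycin against BrefA (548 genes, highest other 2) and Halofuginone against Tunicamycin (1152 genes, highest other 7). They do not for Baflo (8 genes, highest other 121, 2 splits as large) and ZVAD against Caspase-1 (154 genes, highest other 392, 2 splits as large), where chance cannot be excluded. A share of 1 of 35 is the smallest this design allows and was not adjusted over the 14 comparisons. The Caspase-1 count was 3 on plate 2 alone. For ZVAD the real count was 0, so that 35 of 35 splits gave as many by construction and nothing is decided (highest other 40). Other splits of Baflo, ZVAD and ZVAD against Caspase-1 wells called many more genes than the real one, which points to a structure of the samples. In LPS, tBHQ, pGE2, Baflo, ZVAD, Caspase-1, Tunicamycin and ZVAD against Caspase-1 the highest other split was also the one with the largest difference in Rn45s share.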

How the results depend on the processing

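Settings with the Rn45s share as a covariate, Rn45s and Lars2 left out, DMSO wells or letters split, or named wells left out were tests chosen only after the result was seen. Depth limits these data: 25.4% of simulated 1.5-fold and 67.2% of 2-fold changes were recovered in the Baflo comparison. P-values measure the spread between wells, and no count of calls says how many genes did not change. Counts of calls stayed within 1.5 times under RLE scaling, the filter at 20 CPM, the rules for failed libraries, without Rn45s and Lars2, and without Tunicamycin plate 2 F. No named gene past the threshold changed sign under any setting except Flcn in the LPS comparison on plate 2 alone (0.14, adjusted p = 0.933, the cause was not tested). Of named genes 396 of 400 kept their side of the threshold with RLE scaling, and 382 of 382 that had a DESeq2 result. Wells summed gave 366 of 400 and plate 2 alone 279 of 391. With wells summed Il1a (Dexa), Trappc11, Slfn9 and Rps18 (Tunicamycin) and Mxd3, Hnrnpul2, Rgl1, Sptlc2, Ndufc1, Cacna1a, Nmrk1 and Ifi44 (Caspase-1) were not past the threshold.

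Counts of calls that moved by more than 1.5 times follow by setting, and the cause was not tested unless given. Plate 1 alone gave 101 for Dexa, 438 for Torin, 1302 for Halofuginone, 518 for BrefA, 378 for Tunicamycin and 146 for ZVAD against Caspase-1, and plate 2 alone gave 882 for LPS, 48 for Dexa, 328 for Torin, 1114 for tBHQ, 253 for pGE2, 3 for Caspase-1, 1195 for Halofuginone, 487 for BrefA, 5 for Tunicamycin, 373 for Tunicamycin against BrefA, 0 for ZVAD against Caspase-1 and 1365 for Halofuginone against Tunicamycin, each with 4 wells per group in place of 8 (edgeR gave 244 genes at an unadjusted p under 0.05 for ZVAD against Caspase-1 on plate 2). Without the plate term the counts were 59 for Caspase-1 and 10 for ZVAD against Caspase-1, with no filter on low counts 3 for Baflo, 86 for Caspase-1 and 143 for Tunicamycin, and with only the compared groups in the fit 8 for Baflo, 350 for Caspase-1, 1181 for Halofuginone, 112 for Tunicamycin, 548 for Tunicamycin against BrefA, 154 for ZVAD against Caspase-1 and 1152 for Halofuginone against Tunicamycin. Same-named wells summed gave 62 for Caspase-1, 110 for Tunicamycin and 24 for ZVAD against Caspase-1, and the Rn45s covariate in that fit gave 55 for Caspase-1, 1011 for Halofuginone, 136 for Tunicamycin, 29 for ZVAD against Caspase-1 and 893 for Halofuginone against Tunicamycin. The Rn45s covariate with all wells gave 77 for Caspase-1, 1141 for Halofuginone, 23 for ZVAD against Caspase-1 and 1017 for Halofuginone against Tunicamycin. DESeq2 gave 274 for Caspase-1 and 112 for ZVAD against Caspase-1. Without 3 wells (Tunicamycin plate 2 F and plate 1 H, BrefA plate 2 H) the counts were 239 for Caspase-1 and 88 for ZVAD against Caspase-1. Without a well letter the counts were 539 to 662 for Torin (lowest without G), 17 to 71 for Caspase-1 (lowest without E), 96 to 168 for Tunicamycin (lowest without G), 556 to 697 for Tunicamycin against BrefA (lowest without G) and 2 to 18 for ZVAD against Caspase-1 (lowest without F), and within 1.5 times for the other comparisons.

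Letters of compound and DMSO wells do not pair: the mean correlation of their deviations was 0.0109 to 0.142 (0.194 for ZVAD and Caspase-1 wells), and not every pair was over 0.1. A replicate block gave 232 for Caspase-1 and 88 for ZVAD against Caspase-1, and within 1.5 times for the other comparisons; NoStim wells have other letters, so no block was fitted for LPS.

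With an estimated correlation 27 of 66 list calls stayed, on plate 1 alone 58, on plate 2 alone 51, with same-named wells summed 59 and with the Rn45s covariate 61. Lost, beyond those with values given elsewhere, were NRF2 (Halofuginone, Torin), glucocorticoid-induced (Halofuginone), heat shock (Caspase-1), inflammatory (BrefA) and translation (ZVAD) on plate 1, NRF2 (Halofuginone against Tunicamycin, pGE2), interferon (Halofuginone), lysosome (Caspase-1, ZVAD against Caspase-1), macrophage identity (BrefA, LPS), p53 (Halofuginone against Tunicamycin) and translation (LPS) on plate 2, glucocorticoid-induced (Halofuginone), heat shock (Caspase-1), lysosome (ZVAD against Caspase-1), macrophage identity (LPS), p53 (BrefA) and translation (LPS) with wells summed, and NRF2 (Halofuginone, Halofuginone against Tunicamycin), lysosome (Caspase-1, ZVAD against Caspase-1) and translation (LPS) with the covariate. Among expected lists those lost with an estimated correlation were the inflammatory list in Dexa wells (-0.19, adjusted p = 0.160), the translation (0.18, adjusted p = 0.554) and lysosome lists in Torin wells (0.13, adjusted p = 0.105) and the inflammatory list in Caspase-1 wells (0.23, adjusted p = 0.510). That Caspase-1 list was also not called on plate 1 (0.31, adjusted p = 0.0564) or plate 2 alone (0.20, adjusted p = 0.128). Expected lists that became called were NRF2 in tBHQ wells on plate 1 (0.45, adjusted p = 0.0474), lysosome in Baflo wells with same-named wells summed (0.13, adjusted p = 0.0195) and ATF4 in Halofuginone wells with the Rn45s covariate (0.16, adjusted p = 0.0155). Other lists did too, such as translation in tBHQ wells with RLE scaling (0.28, adjusted p = 0.00821), p53 in Torin wells on plate 1 (0.35, adjusted p = 0.0283), glucocorticoid-induced in Tunicamycin wells on plate 1 (0.43, adjusted p = 0.0194) and inflammatory between ZVAD and Caspase-1 with same-named wells summed (-0.21, adjusted p = 0.0113).

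With LPS genes called and measured on both plates together, sharing DMSO wells, medians of repressed genes were 0.21 for Dexa, 0.51 for Torin, 1.18 for tBHQ, 0.18 for pGE2, 0.087 for Baflo, 0.089 for ZVAD, 0.080 for Caspase-1 and 0.20 for BrefA, and that of induced genes -0.48 for BrefA. Shared DMSO wells push these away from 0. Induced genes called on plate 1 and measured on plate 2 had -0.23 for pGE2 and -0.33 for Halofuginone, and the other way -0.31 and -0.76. DMSO wells split between the contrasts gave 0.26 for repressed genes in Torin wells (E and F for LPS) and -0.24 for induced genes in pGE2 wells (G and H for LPS). On the same plate the median r between compounds was 0.293, where simulated unchanged groups gave a mean of 0.470, and r of Torin and Caspase-1 was 0.120 in place of -0.0760 across plates, as shared controls raise it. With DMSO letters split over both plates r of Caspase-1 and Tunicamycin was 0.319 in place of 0.158, and with other letters on the other plate 0.0932. Without Tunicamycin plate 2 F the plate interaction gave 1 gene for Halofuginone against Tunicamycin.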

Other observations

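The comparison of libraries with group profiles and the test of Ifnb1 against a fall were tests chosen only after the result was seen.

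Ifnb1, the interferon beta gene that starts the interferon response, was too low for the gene filter, so its counts were summed by group. It had 2 counts in NoStim wells, 14 in DMSO wells, 32 in BrefA wells and 40 in Halofuginone wells, which is 0.978, 6.60, 15.8 and 50.0 CPM. The other groups had 1.77 to 5.51 CPM.

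The hypothesis that interferon-response genes fell in BrefA wells because less Ifnb1 was transcribed was set before its counts were looked at. The log2 ratio of Ifnb1 in BrefA against DMSO wells was 1.26 (95% counting interval 0.32 to 2.28, exact permutation p = 0.103, n = 8 wells per group), and 1.04 to 1.35 with a letter left out. Against a fall of 0.5 or more the exact permutation p was 0.0192 (one-sided; 0.0143 with wells summed, n = 4), so the tables argue against a fall of that size at 4 h. The bound set beforehand was too weak to exclude the hypothesis, because cells were lysed at 4 h only and transcript made earlier was not measured, and because the gene lies below the filter. Less Ifnb1 transcript before 4 h therefore cannot be told apart from a step after transcription.

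Of 96 libraries 23 were closer to the profile of another group on the other plate than to that of their own: 7 of 8 Tunicamycin, 6 Baflo, 5 ZVAD, 2 DMSO, 2 Caspase-1 and 1 BrefA library. The closest profiles of Tunicamycin plate 2 F were NoStim (r = 0.340), BrefA (0.277) and tBHQ (0.260). Library BrefA plate 2 H had r = 0.382 with BrefA wells and 0.429 with Tunicamycin wells.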
